A study of Mus musculus with 6 samples.

How the data were processed

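Messenger RNA from cultures of mouse spermatogonial stem cells, the germline stem cells of the testis, was sequenced in 6 libraries. Per the labels' protocols, Thy1-positive cells were enriched with magnetic beads from the testes of neonatal pups and grown on mouse embryonic fibroblasts whose division had been stopped with mitomycin C. Lentivirus delivered either a hairpin against Chd4 or a scrambled sequence, EGFP-positive cells were sorted by flow cytometry and kept in culture for a further 5 days. RNA was isolated with Trizol, and polyadenylated RNA was made into Illumina libraries, per the labels' protocols. The strain label names C57BL/6, whereas the growth protocol names the progeny of C57BL6 and DBA/2. Groups were taken from the treatment label, which reads Chd4-KD for 3 libraries and wild type for 3. The titles and file headers call the latter control, and they are called control here. Whether the libraries labelled wild type received the scrambled sequence of the protocol is not said by that label. The design text calls the libraries of a group biological replicates. The labels do not describe how the cultures of the replicates were separated, so the p-values measure the spread between these libraries, part of which may be technical.

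The deposited values are read counts per gene, made by the authors with featureCounts 2.0.1, per the file headers. The header gives paired-end mode, exons as the counted feature, gene identifiers as the unit of summary, no strand option, and the Ensembl release 99 annotation of the mouse build GRCm38. All deposited values were whole-number counts and not estimated counts, so none was rounded. The submitters' processing notes also name Bowtie, DESeq2 and the builds mm8 and mm10, with no role for any of them. Filters before counting are not given in the sources used here. Because no strand option was set, reads of a gene and of its antisense partner cannot be told apart. Genes with near-identical copies, among them ribosomal protein genes and their pseudogenes, histone genes, histocompatibility genes and guanylate-binding protein genes, have uncertain counts, since the default of the counter does not resolve reads that map to several places.

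The table held 55385 genes. Symbols were assigned by exact identifier to 55144 of them, and the other 241 identifiers kept their identifier and took between 0.00379% and 0.00456% of the counts of a library. The 37 mitochondrially encoded genes had 0 counts in each of the 6 libraries and were not tested. Total counts per library ranged from 14741855 to 20868070. Libraries of a group differed by more than sampling noise, with a chi-square of 1.69 to 1.84 per gene between libraries of the same group and 164 to 196 between groups. Separate preparations of 1 culture could differ by as much, so this does not show that the cultures were separate. At that depth a floor of 3 counts corresponded to between 0.142 and 0.184 CPM, counts scaled to a common library total. Intervals and floors given for single genes cover counting error only.

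The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with robust dispersion estimates, TMM scaling, the edgeR expression filter by group and the group as the only term. It was two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 18319 genes that passed the filter. The threshold was an adjusted p of 0.05, and a further count required a change of at least 2-fold, a log2 fold change of 1. CPM values are TMM-scaled and are given as mean ± SD over 3 libraries. Standard errors belong to log2 fold changes of Chd4-KD over control and were derived from the test statistic. For steep changes with few counts in a group they can fall below counting error. The steepest changes are therefore given with the counts of the lower group in place of a standard error. For genes with 0 counts in the controls a lower bound was computed against 3 counts over the control group, and for genes with 1 to 3 control counts a ratio was given with its 95% exact (Clopper-Pearson) counting interval.

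Gene lists were fixed before the data were examined. There were 32, covering the NuRD complex, spermatogonial and germ cell states, apoptosis, the cell cycle, inflammatory and stress responses, metabolism and markers of other cell types, and 31 could be tested. Lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, adjusted over the 31 lists. Camera compares a list with all other genes. Alternatives were camera with an estimated correlation and fry, which asks whether the members of a list move and compares them with no other genes. With an estimated correlation, camera also relies on the few residual degrees of freedom of 6 libraries. Its p-values can then rise even where the estimate lies below 0.01. Some members belong to several lists; 12 of 32 tested members of the undifferentiated spermatogonia list, 7 of 30 p53 targets and 2 of 25 germ cell identity genes were also in another list.

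Genes named in the text followed a rule fixed before the data were examined. They were Chd4, the 10 largest rises and 10 largest falls among genes past the threshold with at least 5 CPM in the higher group, non-overlapping groups and a non-provisional symbol, up to 4 members with the smallest adjusted p of each list past camera or with at least 3 members past the threshold, and a fixed set of spermatogonial, p53 and apoptosis genes with the NuRD subunits. Other genes are named only where they were the exceptions in a list or in the closing observations, and these were chosen after their values were seen.

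Alternatives chosen before the data were examined were DESeq2 size factors, library totals without further scaling, no expression filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, and leaving out each library in turn. The scripts were tested on simulated data made from the means and library sizes of these 6 libraries. In them 50 genes were changed at each of the sizes below, as many up as down, and the rest were unchanged. For the comparison of Chd4-KD with control over 17909 simulated genes, the test recovered 22% of genes changed by 1.1-fold, 54% of those changed by 1.2-fold, 72% at 1.5-fold and 88% at 2-fold. It made 4 false calls among 17715 unchanged genes, and 3 of 100 random unchanged lists had an unadjusted camera p under 0.05. Genes were drawn independently of each other, so the result for lists did not test the effect of correlation between genes. With so few changed genes the adjustment was stricter than in the real comparison, where 74.2% of genes passed. Neither the recovery nor the number of false calls therefore carries over to it, and the simulation did not test the scaling.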

Results

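RNA-seq profiles of mouse spermatogonial stem cell cultures were compared 5 days after sorting of cells infected, per the protocols, with a Chd4 hairpin or a scrambled control. Spermatogonial stem cells sustain sperm production, and CHD4 is the ATPase of the nucleosome remodelling and deacetylase (NuRD) complex. The study asked how CHD4 acts on the survival of these cells. The Chd4-KD libraries held 20868070, 20372148 and 19281238 counts and the control libraries 19038840, 18274358 and 14741855 counts. Libraries of the same group were close to each other, with Pearson correlations of log2 CPM across genes of 0.993 to 0.994 within groups and 0.915 to 0.918 between groups, where genes are not independent replicates. The first principal component held 90.4% of the variance and separated the groups. The common biological coefficient of variation within groups was 2.42%, so small changes passed the test.

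Chd4 (ENSMUSG00000063870, chromosome 6, 125095981 to 125130591, plus strand, GRCm38) was lower in each of the 3 knockdown libraries. Its level was 834, 821 and 838 CPM in Chd4-KD replicates 1, 2 and 3, and 1360, 1355 and 1356 CPM in control replicates 1, 2 and 3. The log2 fold change was -0.71 ± 0.019 (SE), a fall of the mean from 1357 ± 2.79 to 831 ± 8.79 CPM (SD, n = 3), with an adjusted p of 1.2e-34 in the edgeR quasi-likelihood test. Scaled instead to germ cell identity genes, an alternative chosen after seeing the data, the log2 change of Chd4 was 0.035 with an adjusted p of 0.400, or 0.0945 with those genes setting only the difference between groups, also chosen after seeing the data, whereas its adjusted p lay at or below 5.0e-28 in each edgeR and limma-voom alternative chosen beforehand. The other NuRD subunits did not move in a single direction. Of the 14 tested, 7 rose, 4 fell and 3 did not pass, and the list, which holds Chd4 as well, did not pass camera (adjusted p = 0.813). Mbd3, a methyl-CpG-binding domain subunit, rose by 0.73 ± 0.034 on the log2 scale, and Chd3, a paralogue of Chd4, by 0.57 ± 0.026. The histone deacetylase gene Hdac2 had a log2 change of -0.47 ± 0.028, and Gatad2a, Rbbp4 and Rbbp7 had changes of -0.34, -0.18 and -0.21. Mbd2 rose by 0.42, Chd5 by 0.38, Mta1 by 0.30, Mta3 by 0.27 and Cdk2ap1 by 0.26, while Hdac1, Mta2 and Gatad2b had log2 changes of 0.02, 0.01 and -0.03 and did not pass. These counts depended on the scaling. With library totals alone 3 rose (Mbd3, Chd3 and Mbd2), 7 fell and 4 did not pass: Hdac1, Mta2 and Gatad2b were then lower (log2 changes -0.28, -0.29 and -0.33), Chd5 (0.08, adjusted p = 0.138) and Mta1 (0.00, adjusted p = 0.935) lost their calls, Mta3 and Cdk2ap1 turned to -0.03 and -0.04 without passing, and the median of the NuRD list was -0.28 in place of 0.02.

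Knockdown was accompanied by broad changes in transcript levels. Of 18319 genes tested, 6942 were higher and 6649 lower in Chd4-KD, together 74.2%, and 4728 did not pass. At least 2-fold changes were found for 2857 higher and 1332 lower genes. The groups did not overlap for 75.4% of genes, where chance gives 10%. The balance of directions depended on the scaling. Library totals alone moved each log2 value by about -0.30 and gave 4840 higher and 9682 lower genes, so the share of higher genes among those past the threshold was 33.3% in place of 51.1%, and among 2-fold changes 42.7% in place of 68.2%. Scaled to germ cell identity genes, chosen after seeing the data, 13408 genes were higher and 931 lower, with 6713 and 220 of them at 2-fold or more. Changes below are relative to the TMM scaling.

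The steepest rises were in acute-phase, chemokine and interferon-induced genes. Saa3, which encodes the acute-phase protein serum amyloid A3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700, minus strand), went from 0.344 ± 0.0364 to 2342 ± 58.2 CPM, a log2 change of 12.69 from 20 counts over the 3 control libraries. The T-cell chemokine genes Ccl5, Cxcl9 and Cxcl10 rose by 10.97, 10.60 and 10.02 on the log2 scale, from 4, 9 and 51 counts over the 3 control libraries. Lcn2, which encodes the iron-scavenging protein lipocalin 2, had 2 counts over the 3 control libraries and 9063 over the Chd4-KD libraries, a ratio of 4796 (95% counting interval 1327 to 39610). The neutrophil chemokine gene Cxcl2 had 3 and 8685 counts, a ratio of 3064 (interval 1048 to 14861). Acod1, the itaconate-producing enzyme of activated macrophages, had 0 control counts and was at least 1352-fold higher, Cxcl3 at least 747-fold, the interferon-inducible gene Ifi214 at least 201-fold and Clec4e, a C-type lectin receptor, at least 115-fold, each against a floor of 3 counts over the control group.

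The interferon response and TNF and NF-kB response lists rose throughout. All 36 tested interferon response genes rose, each by at least 2-fold, with a median log2 change of 5.35 (camera adjusted p = 1.0e-17). Ifit3 went from 8.60 ± 0.345 to 1552 ± 34.8 CPM, Ifit1 rose by 7.43 on the log2 scale (396 control counts), and Bst2, which encodes the virus-tethering protein tetherin, by 4.55 ± 0.027. All 29 genes of the TNF and NF-kB list rose, 28 of them by at least 2-fold, with a median of 4.37 (adjusted p = 2.8e-13), also with the 2 genes that had 0 control counts set at their bounds. The neutrophil chemokine genes Cxcl5 and Cxcl1 rose by 8.60 and 8.73, from 235 and 121 control counts. The monocyte chemokine gene Ccl7 rose by 6.00, from 672 control counts, and the adhesion molecule gene Vcam1 by 4.80 ± 0.031. Fibroblast and extracellular matrix genes rose with these genes (31 of 36, median 1.47), while leukocyte markers stayed at low levels, as given below.

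**Figure D1:**
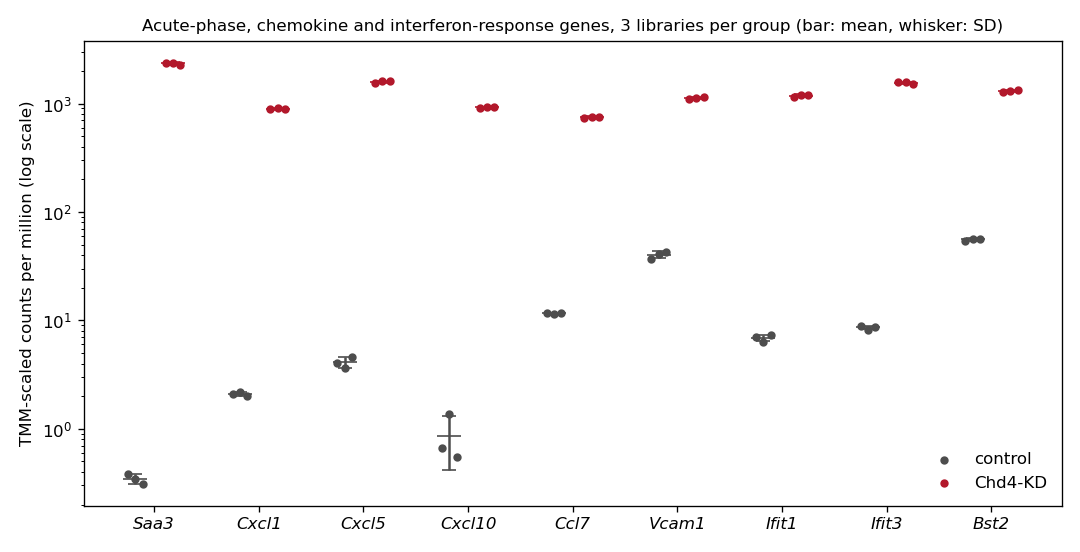
TMM-scaled CPM on a log axis for 9 acute-phase, chemokine and interferon-response genes in the 3 control and 3 Chd4-KD libraries, with a point per library, a bar at the mean and whiskers of 1 SD. Saa3 averaged 2342 CPM in Chd4-KD and 0.344 CPM in controls, and Ifit3 1552 and 8.60 CPM.

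Genes of undifferentiated spermatogonia fell. Of 32 tested, 26 fell, 1 rose and 5 did not pass, with a median log2 change of -0.79 (camera adjusted p = 1.7e-07). Gfra1, a co-receptor for the stem cell factor GDNF (ENSMUSG00000025089, chromosome 19, 58235604 to 58455909, minus strand), went from 259 ± 2.74 to 81.1 ± 1.87 CPM, a log2 change of -1.67 ± 0.030. The transcription factor genes Sall4, Id4 and Bcl6b had log2 changes of -1.66 ± 0.041, -1.43 ± 0.053 and -1.48 ± 0.032. The stem cell-enriched genes Lhx1 and Plvap had changes of -2.55 ± 0.055 and -2.50 ± 0.056, and Zbtb16, which encodes PLZF, had -0.80 ± 0.027. The steepest fall among all named genes was that of T, which encodes brachyury, from 18.0 ± 0.0446 to 0.910 ± 0.291 CPM (log2 change -4.29, with 50 Chd4-KD counts), and Eomes fell from 6.21 to 0.990 CPM. Upp1, a uridine phosphorylase gene, was the exception that rose, with a log2 change of 1.87. Among genes that respond to GDNF and FGF, 18 of 25 fell and 5 rose (adjusted p = 5.8e-03), with an adjusted p = 0.0787 with an estimated correlation. Etv5, a GDNF-induced transcription factor gene, went from 305 ± 6.38 to 165 ± 4.44 CPM. The 5 that rose were Ccnd1 (0.90 ± 0.026), Fgfr2, Spry2, Fgfr1 and Ccnd2. In the same libraries germ cell identity genes had a median of -0.76 and fibroblast and extracellular matrix genes one of 1.47.

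Other germ cell genes were lower as well. Of 25 germ cell identity genes, 23 fell and 2 rose, with a median of -0.76 (adjusted p = 3.0e-07, and adjusted p = 0.0839 with an estimated correlation). The germline RNA-binding protein gene Dazl had a log2 change of -0.96 ± 0.022, and the RNA helicase gene Ddx4 from 399 ± 7.67 to 195 ± 6.17 CPM. Mov10l1 and Piwil2, genes of the piRNA pathway, had log2 changes of -1.09 ± 0.028 and -0.92 ± 0.025, while Dppa3, at 8.79 CPM against 3.80 CPM, and Dpep3, at 40.8 CPM against 34.2 CPM, rose. Of 31 meiosis genes, 28 fell and none rose (median -0.79, adjusted p = 4.5e-08), with changes of -1.08 ± 0.032 for the cohesin gene Smc1b, -1.02 ± 0.038 for Sycp2 and -0.74 ± 0.029 for Stag3. Relative to 23 germ cell identity genes, a scaling chosen after seeing the data, 13 of the 32 undifferentiated spermatogonia genes were lower, 10 higher and 9 did not pass. The edgeR test was the same, but its coefficient of variation, estimated again, was 3.71% in place of 2.42%. With TMM kept within groups and the germ cell identity genes setting only the difference between them, also chosen after seeing the data, that coefficient was 2.42% and 14 were lower, 10 higher and 8 did not pass. Zbtb16 had a log2 change of -0.06 with each of the 2 and did not pass. Fibroblast and extracellular matrix genes rose in the same libraries (31 of 36, median 1.47).

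Genes of differentiating spermatogonia moved both ways. Of 15 tested, 8 fell and 4 rose (adjusted p = 0.193). Kit, the receptor that marks differentiating spermatogonia, rose from 11.3 ± 1.11 to 15.4 ± 0.948 CPM, and had a log2 change of 0.15 with an adjusted p of 0.129 when library totals alone were used for scaling. The retinoic acid target gene Stra8 had a log2 change of -0.79 ± 0.076, but -0.04 (adjusted p = 0.652 and 0.600) with the 2 scalings to germ cell identity genes, and Sohlh2 and Dmrt1 had log2 changes of -0.85 ± 0.035 and -0.64 ± 0.027, whereas the retinoid genes Crabp1 and Rarg rose by 0.93 ± 0.025 and 0.91 ± 0.037. In the spermiogenesis list 8 of 12 fell and 2 rose (adjusted p = 0.134), and Tssk1 and Tekt1 stood at 1.26 and 1.78 CPM in Chd4-KD against 4.41 and 5.23 CPM in controls. Of 13 pluripotency genes, 9 fell and 1, Klf4, rose (adjusted p = 7.2e-03, and adjusted p = 0.0839 with an estimated correlation). Lin28a and Lin28b had log2 changes of -0.68 ± 0.031 and -1.19 ± 0.058. The median of the pluripotency list was -0.57, in libraries where that of germ cell identity genes was -0.76 and that of fibroblast and extracellular matrix genes 1.47.

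**Figure D2:**
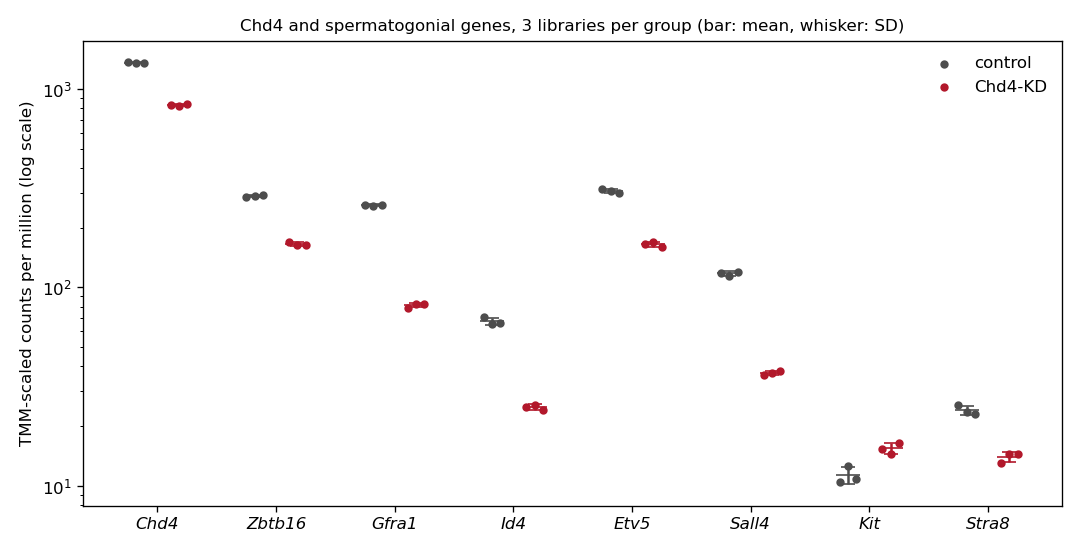
TMM-scaled CPM on a log axis for Chd4 and 7 spermatogonial genes in the 3 control and 3 Chd4-KD libraries, with a point per library, a bar at the mean and whiskers of 1 SD. Chd4, Zbtb16, Gfra1, Id4, Etv5, Sall4 and Stra8 were lower in Chd4-KD, and Kit was higher (15.4 against 11.3 CPM) under the TMM scaling. The difference in Kit did not pass with library totals alone, and those in Chd4, Zbtb16 and Stra8 did not pass with either scaling to germ cell identity genes.

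Cell cycle genes fell and p53 target genes rose. All 30 mitosis genes fell, with a median of -0.72 (adjusted p = 1.6e-10), including the proliferation marker Mki67 (262 ± 5.44 to 130 ± 3.66 CPM) and the topoisomerase gene Top2a (-0.79 ± 0.024). Of 34 genes of DNA replication and S phase, 31 fell and 1, Chaf1b, rose (adjusted p = 1.9e-08), and Uhrf1, which couples replication to DNA methylation, fell from 398 ± 8.50 to 174 ± 7.60 CPM. Of 30 p53 targets, 27 rose and 2, Sesn1 and Ckap2, fell, with a median of 1.17 (adjusted p = 8.4e-08). Cdkn1a, which encodes the CDK inhibitor p21 (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727, plus strand), went from 153 ± 0.825 to 864 ± 16.5 CPM, a log2 change of 2.50 ± 0.024. Ccng1, Plk2 and Mdm2 rose by 1.79 ± 0.025, 2.25 ± 0.033 and 1.33 ± 0.024, and Trp53 itself by 0.60 ± 0.031. The list of 7 CDK inhibitors did not pass (4 rose, 2 fell, adjusted p = 0.205). Cdkn2b and Cdkn2a rose by 2.03 ± 0.038 and 1.23 ± 0.032, while Cdkn1c and Cdkn1b fell, with log2 changes of -1.02 and -0.78. Cell type markers moved in the same libraries: germ cell identity genes had a median of -0.76, against -0.72 for mitosis and -0.64 for DNA replication and S phase, and fibroblast and extracellular matrix genes a median of 1.47, against 1.17 for p53 targets. The cells had been grown on fibroblasts whose division was stopped with mitomycin C. Whether a changed mix of cells gave either shift was not tested, so neither can be assigned to the stem cells.

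Genes on both sides of apoptosis rose. Of 27 pro-apoptotic genes, 19 rose and 8 fell (adjusted p = 0.0247, and adjusted p = 0.121 with an estimated correlation). Fas, which encodes a death receptor, rose from 6.85 ± 0.462 to 72.2 ± 2.15 CPM, the death receptor gene Tnfrsf10b by 1.29 ± 0.039 on the log2 scale, the mitochondrial pore gene Bak1 by 2.48 ± 0.064 and Bax by 0.74 ± 0.031. Of 10 anti-apoptotic genes, 9 rose and none fell (adjusted p = 7.0e-04, and adjusted p = 0.0839 with an estimated correlation). Birc3, an inhibitor of apoptosis gene, rose by 2.31 ± 0.069, the caspase-8 regulator Cflar by 1.82 ± 0.035, the co-chaperone gene Bag3 by 1.12 ± 0.040 and Bcl2 from 2.21 ± 0.431 to 3.73 ± 0.243 CPM. The medians were 0.59 for pro-apoptotic and 0.95 for anti-apoptotic genes, in libraries where 31 of 36 fibroblast and extracellular matrix genes rose (median 1.47) and 23 of 25 germ cell identity genes fell (median -0.76).

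Markers of other cell types differed between the groups. Of 36 fibroblast and extracellular matrix genes, 31 rose and 5 fell, with a median of 1.47 (adjusted p = 1.9e-08). The collagen cross-linking enzyme gene Lox went from 126 ± 4.30 to 1252 ± 21.4 CPM, and the matrix proteoglycan genes Dcn and Bgn from 168 ± 0.865 to 1122 ± 18.4 and from 511 ± 7.64 to 2522 ± 22.7 CPM. The 5 that fell were Col6a1, Col6a2, Col6a3, Fap and Timp3, with log2 changes from -1.45 for Fap to -0.23 for Col6a1. Of 14 Sertoli cell genes, 9 rose and 1 fell (adjusted p = 6.1e-03, and adjusted p = 0.0976 with an estimated correlation). The lysosomal protease gene Ctsl rose by 3.04 ± 0.021 and the inhibin subunit genes Inhba and Inhbb by 3.82 ± 0.040 and 1.63 ± 0.037, while Wt1 and Gata4, transcription factor genes of the Sertoli lineage, had changes of 0.15 and -0.18 and did not pass. In the macrophage and leukocyte list 8 of 11 rose and 2 fell (adjusted p = 0.201). Lyz2 stood at 18.1 ± 1.33 CPM in Chd4-KD and 11.1 ± 1.15 CPM in controls, Cd14 at 14.8 and 2.18 CPM, and Mrc1 at 0.813 and 4.31 CPM. Of 11 endothelial genes, 6 rose and 4 fell (adjusted p = 0.593), among them Eng with a rise of 2.14 ± 0.063 and Kdr with a log2 change of -2.74 ± 0.14. The Leydig and peritubular myoid list (4 of 7 rose, adjusted p = 0.194) and the somatic lineage transcription factors (9 of 18 rose, 3 fell, adjusted p = 0.186) did not pass, though Nr2f2, Acta2 and Runx1 rose by 1.96 ± 0.062, 1.65 ± 0.083 and 2.08 ± 0.065. Tagln passed with an adjusted p of 0.0261 and lost the call in DESeq2 and on leaving out Chd4-KD replicate 1 or 2 or control replicate 1 or 3, with adjusted p values of 0.0621 to 0.111 in those fits, and 0.146 with library totals alone.

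**Figure D3:**
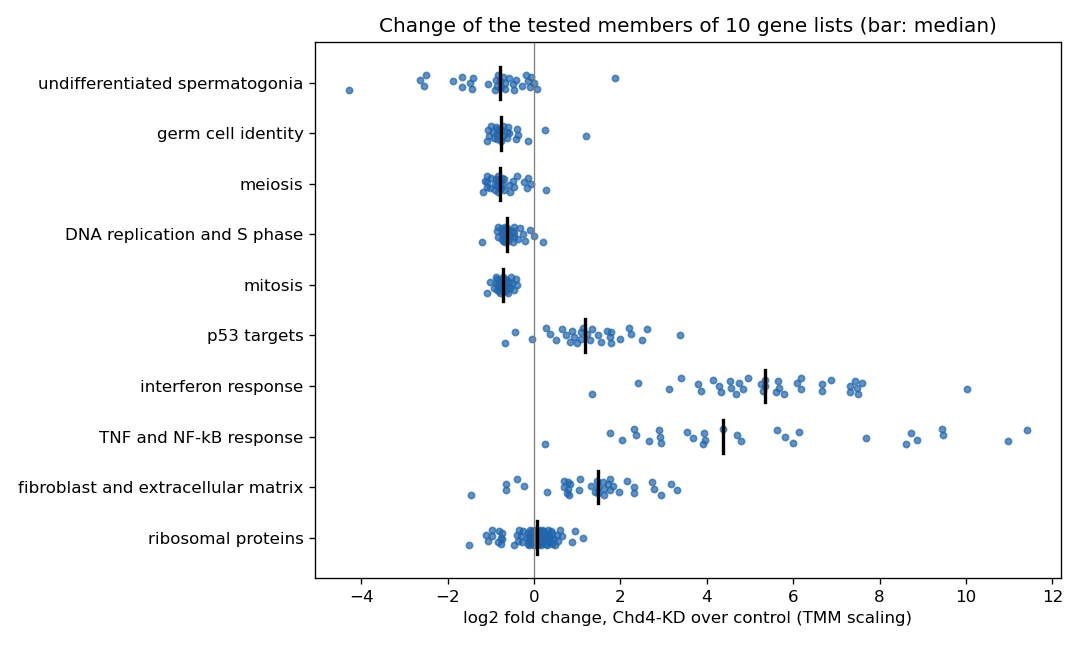
Log2 fold change of Chd4-KD over control under TMM scaling for each tested member of 10 gene lists, with a point per gene and a bar at the median of the list. The medians ran from -0.79 for undifferentiated spermatogonia to 5.35 for the interferon response, and that of the ribosomal proteins was 0.06 and turned to -0.24 with library totals alone.

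Stress and metabolic genes changed in several directions. Immediate early genes rose in 18 of 22 cases and fell in 2 (Egr1 and Nr4a1), with an adjusted p of 2.4e-04, and Junb, Jun and Socs3 rose by 2.08 ± 0.038, 2.00 ± 0.042 and 1.80 ± 0.034. Of 25 genes of the unfolded protein and integrated stress responses, 20 rose and 3 fell (adjusted p = 5.8e-04). The cystine transporter gene Slc7a11 rose from 2.36 ± 0.440 to 116 ± 1.79 CPM, and Cebpb and Nupr1 by 3.61 ± 0.056 and 3.17 ± 0.063. The medians of the 2 lists were 0.89 and 0.54, in libraries where 31 of 36 fibroblast and extracellular matrix genes rose (median 1.47) and 23 of 25 germ cell identity genes fell (median -0.76). Of 21 cholesterol synthesis genes, 13 fell and 6 rose (adjusted p = 0.0308, adjusted p = 0.254 with an estimated correlation and 0.0527 with the replicate number as a block), with Hmgcs1 at -0.74 ± 0.030 and Sc5d at 1.13 ± 0.044. Of 27 oxidative phosphorylation genes, 18 rose and 4 fell (adjusted p = 0.0438, and adjusted p = 0.121 with an estimated correlation), and the median of 0.19 turned to -0.11 with library totals alone. That list did not pass with a filter of at least 1 CPM in 3 libraries (adjusted p = 0.0776), without control replicate 1 (0.0580), without control replicate 2 (0.0566) or with the replicate number as a block (0.0539). The glycolysis and hypoxia list split into 11 rises and 11 falls (adjusted p = 0.667), with a median of 0.04 and a mean of -0.43. The glucose transporter gene Slc2a3, Pfkp and Pdk1 had log2 changes of -2.54 ± 0.038, -2.21 ± 0.036 and -1.85 ± 0.039, while Ldha rose by 0.81 ± 0.024. The hypoxia-induced genes Ankrd37 and Ndufa4l2 were among the 10 steepest falls, with log2 changes of -3.46 (76 Chd4-KD counts) and -2.62 ± 0.13. The remaining steepest falls were those of Zscan5b (-2.98), Scara5 (-2.92), Kdr, Grm4 (-2.67), Zfp385c (-2.67) and Col6a5 (-2.64).

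Imprinted genes, of which 12 of 25 fell and 9 rose (adjusted p = 0.524), and DNA methylation genes, of which 7 of 14 fell and 6 rose (adjusted p = 0.744), showed no common direction. Impact rose by 1.63 ± 0.033 and Tet2 by 1.39 ± 0.068, while Peg3, H19 and the maintenance methyltransferase gene Dnmt1 had log2 changes of -1.03 ± 0.032, -0.47 ± 0.020 and -0.67 ± 0.024. The median of the DNA methylation list was 0.04 although camera placed the list lower than other genes. Of 85 ribosomal protein genes, 39 rose and 28 fell (adjusted p = 0.744), from Rpl34 at -1.11 ± 0.028 to Rps27l at 1.13 ± 0.031 among those named, with a median of 0.06 and a mean of -0.00. The medians of the DNA methylation, glycolysis, endothelial and ribosomal lists changed sign with library totals alone, to -0.26, -0.26, -0.12 and -0.24. Of 33 replication-dependent histone genes, whose messages largely lack poly(A) tails, 17 rose and 3 fell (adjusted p = 0.0834, but 0.0112 with the filter of at least 1 CPM in 3 libraries and 0.0461 without Chd4-KD replicate 1), and Hist1h2bc rose by 1.85 ± 0.059.

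Adjusted over the list alone, the counts were the same as over all genes tested for 26 of the 31 lists. In the others, adjusted over the list alone, 2 undifferentiated spermatogonia genes rose in place of 1, 0 Sertoli cell genes fell in place of 1, 14 cholesterol synthesis genes fell in place of 13, 12 glycolysis and hypoxia genes rose in place of 11, and 16 histone genes rose and 2 fell in place of 17 and 3. In all, 18 lists passed camera, 10 of them higher and 8 lower. With an estimated correlation 10 of these held, namely undifferentiated spermatogonia, meiosis, p53 targets, DNA replication and S phase, mitosis, TNF and NF-kB response, interferon response, fibroblast and extracellular matrix, immediate early genes and the unfolded protein and integrated stress responses. Among the lists that lost the call, some had an estimate below the preset 0.01, such as GDNF and FGF responsive genes (-0.029). Others had one above it, such as germ cell identity genes (0.12). A call lost in that fit therefore need not reflect correlation between genes. Splits of the 6 libraries that mixed the groups gave 11 to 16 lists past camera.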

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

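The 2 scalings to germ cell identity genes were chosen after seeing the data, and the other alternatives before. The numbers of genes higher and lower, and of those changed at least 2-fold, stayed within 1.5 times the main counts under each alternative chosen beforehand, with 1 exception: library totals alone gave 2798 genes lower by at least 2-fold, against 1332, because that scaling moved each log2 value by -0.30. Scaling to germ cell identity genes gave 13408 higher and 931 lower genes, 6713 and 220 of them by at least 2-fold, and 13451, 966, 6696 and 218 when these genes set only the difference between groups, because each log2 value moved by about 0.74. DESeq2 gave 6552 higher and 5925 lower genes, and 12469 of the 13591 main calls were shared in direction. Leaving out 1 library gave 6843 to 6894 higher and 6247 to 6456 lower genes, with 2923 to 3006 and 1373 to 1445 of them past 2-fold. The log2 change of Chd4 lay between -1.01 and -0.69 under the alternatives chosen beforehand, and was 0.0354 (adjusted p = 0.400) when scaled to germ cell identity genes and 0.0350 (adjusted p = 0.0945) when these set only the difference between groups, because those genes had fallen by about as much. The number of lists past the threshold was 18, 10 for camera with an estimated correlation, and 29 for fry, which compares a list with no other genes, and 17 to 19 when 1 library was left out.

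Among the other named genes, 147 of 156 kept direction and call with library totals alone, Chd5, Mta1, Kit and Tagln lost their calls, Gatad2b gained one, and 4 turned: Hdac1 (-0.28), Cdk2ap1 (-0.0430), Mta3 (-0.0324) and Mta2 (-0.29). Mta2, near 0 in the main test, also stood at -0.0113 with a filter of at least 1 CPM in 3 libraries and at -0.0084 without control replicate 2, with up to 0.0163 when other libraries were left out. The cause was not tested. Over the 6 fits without 1 library, 914 calls of these genes were kept and 4, all of Tagln, were lost, and 106 list calls were kept, 2 lost and 1 gained. The ribosomal protein list turned with the filter of at least 1 CPM in 3 libraries (adjusted p = 0.999). Zbtb16 and Stra8 lost their calls in both scalings to germ cell identity genes. In place of 26 undifferentiated spermatogonia genes, 13 were lower when each library was so scaled, which also raised the coefficient of variation to 3.71%, and 14 with TMM kept within groups. The libraries showed little sign of pairing by replicate number: deviations of libraries with the same number correlated at -0.00 to 0.02 across genes. Still, 4 of 6 libraries correlated best with their own number, so pairing is not excluded. With the replicate number as a block, 6926 genes were higher and 6586 lower, and the lists of cholesterol synthesis (adjusted p = 0.0527) and oxidative phosphorylation (adjusted p = 0.0539) did not pass. In simulated data with 50 genes changed at each size, 22% of 1.1-fold and 54% of 1.2-fold changes were recovered. These rates do not carry over to the real comparison, where far more genes passed and the adjustment was less strict.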

Other observations

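All gene families in the next 2 paragraphs, and the tests of explanations after them except the counts over splits of the libraries, were chosen after the values were seen. The denominator of the leukocyte test was changed after a first value had been seen, with the same outcome. The fibroblast test of the inflammatory genes was computed again without a cap on standard errors that had favoured its result. A further test, of the rise of fibroblast genes, was run and left out. Its value was the 5 of 36 fibroblast and extracellular matrix genes that fell. Log2 changes in that list ran from -1.45 to 3.31. Antigen presentation and cell-intrinsic defence genes rose in Chd4-KD, in libraries where 31 of 36 fibroblast and extracellular matrix genes rose (median 1.47) and 23 of 25 germ cell identity genes fell (median -0.76). Of 22 chemokine genes tested, 21 rose and 1, Ccl25, fell (camera adjusted p = 7.8e-09 over 12 families), and Ccl2 reached 1978 CPM against 9.79 CPM in controls. All 10 guanylate-binding protein genes rose (adjusted p = 4.5e-06, and adjusted p = 0.0516 with an estimated correlation), as did all 6 immunity-related GTPase genes (adjusted p = 1.2e-04, and adjusted p = 0.0587 with an estimated correlation) and all 6 Schlafen genes (adjusted p = 2.9e-04). Of 24 histocompatibility genes, 21 rose and none fell (adjusted p = 2.8e-06), among them H2-D1 (99.2 to 2492 CPM) and H2-K1 (46.1 to 1300.2 CPM). Of 38 proteasome genes, 35 rose and 2 fell (adjusted p = 1.1e-06, and adjusted p = 0.0516 with an estimated correlation), led by the immunoproteasome subunit genes Psmb8 (log2 change 5.60), Psmb9 (3.39) and Psmb10 (2.80), while Psma8, the testis-specific subunit gene, had -1.11. Complement genes rose in 15 of 17 cases and fell in 2 (adjusted p = 9.3e-06), with C3 at 635 CPM against 8.19 CPM.

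Among secreted proteases and developmental genes, 17 of 19 matrix metalloproteinase genes rose and 1 fell (adjusted p = 3.6e-06), with Mmp3 at 2649 CPM against 88.4 CPM, beside the medians of 1.47 for fibroblast and extracellular matrix genes and -0.76 for germ cell identity genes. Collagen genes split, with 22 of 42 rising and 13 falling (adjusted p = 0.161). Of 32 Hox genes, 23 rose and 3 fell (adjusted p = 8.1e-04, and adjusted p = 0.0589 with an estimated correlation), with Hoxc6 at 1.73 and Hoxb8 at -0.75 on the log2 scale. Of 352 genes with Zfp symbols, 178 fell and 89 rose (adjusted p = 5.9e-03, and adjusted p = 0.0589 with an estimated correlation). Histone deacetylase and sirtuin genes showed no common direction (9 of 18 rose, 6 fell, adjusted p = 0.969), and their median of 0.06 turned to -0.24 with library totals alone. The X-inactivation transcript Xist rose from 96.4 ± 2.07 to 245 ± 8.58 CPM (SD, n = 3), whereas the Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d had log2 changes of 0.15, -0.13, -0.17 and -0.32.

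Germ cell genes fell together with a rise of fibroblast genes in cells that had been grown on fibroblast feeders. The X-inactivation transcript Xist rose as well, by 1.34 on the log2 scale, beside a fibroblast and extracellular matrix median of 1.47. The Y-linked genes given above changed by -0.32 to 0.15. What these values say about the mix of cells was not tested. A smaller share of germ cells as the whole cause is argued against for part of the stem cell genes, since 9 of the 32 undifferentiated spermatogonia genes, among them Gfra1, Sall4, Id4, Bcl6b and Lhx1, fell more than Mov10l1, the steepest-falling of the other germ cell identity genes (log2 change -1.09), by over 3 standard errors. Falls steeper than that of Mov10l1 were not particular to stem cell genes, though the rule of 3 standard errors was not applied to other lists. The lowest log2 changes were -1.18 in the meiosis, -1.79 in the spermiogenesis and -2.12 in the differentiating spermatogonia list. For germ cell identity genes themselves a smaller share stays open. The 5 most abundant of them spanned 0.692 on the log2 scale. That was wider than the limit set for a smaller share and narrower than the limit set against it, so it does not decide. No spread of this kind, whatever its width, could exclude a smaller share acting beside other changes. A loss of stem cells among the germ cells and lower expression per cell cannot be told apart in bulk RNA. The EGFP sort preceded the last 5 days of culture, and whether feeder cells were present in those days is not given in the sources used here. Fibroblast genes were abundant in controls too, where Col1a1 and Col3a1 stood at 1934 and 2227 CPM, against 954 CPM for Dazl. Which cells these transcripts came from was not tested.

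Interferon and NF-kB genes rose in all of their 65 tested members. Leukocytes as the source of most of this summed rise are argued against, because 18 leukocyte markers summed to 53.2 CPM in Chd4-KD, 0.220% of the 24190 CPM by which the 65 genes rose. The markers rose too, from a sum of 30.6 CPM in controls. The ratio of markers to inflammatory transcripts within leukocytes was not measured. For less abundant genes, such as Acod1 and Clec4e, a leukocyte source is not excluded. A larger share of fibroblasts as the whole cause is also argued against, since 49 of the 65 rose more than Lox, the steepest-rising fibroblast marker (log2 change 3.31), by over 3 standard errors, though a response within fibroblasts is not excluded. These standard errors can fall below counting error for genes with few control counts, so the number 49 may be too high. A difference between the cultures other than the hairpin, such as virus dose or a microbial contaminant, cannot be told apart from the knockdown, because each group may have been handled apart and the biological coefficient of variation within groups was only 2.42%. A response of knockdown cells to the loss of CHD4 is a further hypothesis that these data do not test.

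The fall of Chd4 was of the size of the fall of germ cell genes. Scaled to 23 germ cell identity genes, the Chd4 log2 change was 0.0354 ± 0.0387 (SE), within the SD of 0.49 of those genes. A smaller germ cell share with unchanged Chd4 per germ cell and a knockdown within germ cells therefore cannot be told apart, since CHD4 may itself act on the reference genes. Whether fibroblasts express Chd4 was not measured. If they do, a smaller germ cell share would lower Chd4 by less than genes restricted to germ cells. The mRNA level in sorted germ cells or the protein was not analysed here.

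With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 13591 genes past the threshold and 4189 past it at 2-fold or more, and the highest of the other 9 splits gave 0 genes in both cases by edgeR, with at most 107 genes at an unadjusted p under 0.05. In each of the 3 counts only 1 split, the real one, gave as many. For the lists, the real split gave 18 and the others 11 to 16. Each of the other splits still sets 2 libraries of a group against 1, which leaves part of the group difference in the camera test.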
